A study of Mus musculus with 11 samples.

How the data were processed

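Messenger RNA of whole kidneys was sequenced in a mouse model of Alport syndrome. The 11 libraries fall into 3 groups by genotype and treatment, as the labels give them: Col4a3+/- mice given PBS (HET PBS, n = 3), Col4a3-/- mice given PBS (KO PBS, n = 4) and Col4a3-/- mice given antimiR-21 (KO antimiR-21, n = 4). Libraries were made from 150 ng of total RNA with the TruSeq RNA v2 kit, per the labels' protocols. That kit does not mark the strand of a transcript. The submitters' processing notes name FastQC, STAR, SAMtools, HTSeq 0.5.4p5, limma and the genome build mm10, without saying which step each served. The gene annotation, the aligner's version and the counting settings are not given in the sources used here.

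The deposited file of each library holds estimated counts per gene symbol or unnamed locus, not normalized, per the file headers and the values. Values came in steps of 0.5, and 47.4% of the values above 0 were not whole. The authors also deposited a matrix of log2 values for the whole series. Each of its columns differed by a constant from the log2 CPM of the same library computed with 0.5 added to each count, so it carries the same measurements after a scaling of the library sizes, and it was used only as an alternative. Its columns of other samples numbered 0.

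Each file had 24914 rows. For 1513 pairs of names the count was identical in all 11 libraries with a total of at least 50, and such a pair was joined into a joint locus, written with a slash, so that its reads entered once. Of the 1121 pairs with both names in the annotation, 94.3% lay within 10 kb of each other, 63.3% overlapped and 96.9% were on opposite strands. The reads of a joint locus cannot be assigned to either of its genes. This joining was chosen after the files were examined, and rows as deposited were run as an alternative. Unnamed loci held 1.35% of the counts. Total counts per library ran from 22.4 to 49.7 M as deposited and from 17.9 to 39.7 M after joining. Gene coordinates come from GENCODE vM21 on GRCm38, the build that mm10 names, which may differ from the annotation used for counting.

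Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Loci were kept by filterByExpr over the 3 groups, which left 14380 loci (1502 of them joint), and library sizes were scaled by TMM. A quasi-likelihood model (glmQLFit, robust) was fitted to all 11 libraries with 3 groups, which share 1 estimate of the spread, and 3 comparisons were tested two-sided with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.215. Fixed gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 37 lists with 3 or more tested members. Camera with an estimated correlation and fry, a rotation test of whether a list's genes move on balance in 1 direction (its mixed test takes changes in either direction), were run beside it. The mitochondrial genome list had 0 members in the counts used here and gave no result. For a list score, each member's log2 CPM minus its HET PBS mean was averaged per library, and groups were compared by an exact two-sided permutation test. With 3 libraries against 4 that test has 35 arrangements and with 4 against 4 it has 70, and the smallest p it gives with 70 is 0.0286.

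Comparisons, tests, lists, the alternatives called planned and the rule for named genes were set before the data were examined. The rule took up to 6 genes per direction among those past the adjusted threshold with a mean of at least 5 CPM and group ranges that do not overlap, or, where no gene passed, the 5 genes with the smallest p. It added the 2 members with the smallest p of every list that passed in a comparison. It also took Col4a3, Col4a4, Col4a5, Vmp1, Ddx3y and, for the treatment, a set of miR-21 targets reported before (Spry1, Reck and Ppara among them). Mir21a, Pdcd4, Timp3, Mpv17l and Xist, which the rule also names, were not analysed here. Results of some genes that the rule takes are not reported here. Where a single gene passed the threshold outside the rule it is named and said to be so.

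The disease score of a library is the mean, over genes that differ between HET PBS and all 8 KO libraries, of the sign of that difference times the log2 CPM minus the HET PBS mean. For the reversal, genes of KO PBS against HET PBS were followed in KO antimiR-21 against KO PBS. Both comparisons share the KO PBS libraries, so 50 sets of unchanged groups were simulated with the observed spread, and the KO PBS libraries were also divided in 6 ordered ways between the comparisons. For miR-21 sites, the longest annotated 3 prime UTR of each gene was searched for ATAAGCT, the 7-base match to the miR-21-5p seed, and joint loci were left out. Of the 52034 transcripts with such a UTR, 99.9% had a UTR that began with a stop codon, a check of its coordinates.

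The labels give no sex. Libraries with a Ddx3y level above 5 CPM are called libraries with Y-linked reads, and this status was used as a covariate in alternatives. Replicates were compared in pairs by a chi-square test of their counts over genes with at least 20 reads. Its lowest value per degree of freedom was 6.17, so no pair differed by as little as sampling noise. The labels do not tie libraries to named animals, so p-values measure the spread between these libraries. The gene test was tested on simulated counts with the means and library sizes of these data, 3 draws of 100 loci changed 2-fold and 100 changed 4-fold among 14380. For KO PBS against HET PBS it recovered 60.3% of 2-fold and 89% of 4-fold changes, with 4.48% of its calls false. For KO antimiR-21 against KO PBS these shares were 63.3%, 88.7% and 5%, and for KO antimiR-21 against HET PBS 58.3%, 90.3% and 3.88%. Each locus was drawn independently, without the differences by Y-linked status that loci share in these data. The shares therefore need not hold for the real libraries. Alternatives were other normalizations, filters and tools (DESeq2 1.42.0, limma-voom, limma on the deposited log2 matrix), fits with fewer samples, a replicate block, the Y-linked covariate, the 20 most abundant genes left out, and each library left out in turn. Permutations of scores and figures used R and Python 3.11.15.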

Results

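Whole kidneys of 129X1/SvJ mice were profiled by mRNA sequencing at 5.5 weeks of age in the Col4a3 knockout model of Alport syndrome. In this inherited kidney disease the type IV collagen network that contains the Col4a3 chain is lost from the glomerular basement membrane. The groups were 3 heterozygous kidneys given PBS (HET PBS), 4 knockout kidneys given PBS (KO PBS) and 4 knockout kidneys given antimiR-21, an oligonucleotide inhibitor of the microRNA miR-21 (KO antimiR-21). Total counts ran from 17.9 to 39.7 M per library. TMM factors ran from 0.917 to 1.08, and the 10 most abundant loci took 6.52% to 7.78% of the counts. Values below are CPM (counts scaled to a common library size), as mean ± SD over the libraries of a group, and log2 differences with their standard error (SE).

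Col4a3, the targeted gene, encodes the alpha-3 chain of type IV collagen and lies on chromosome 1 from 82586921 to 82722059 (GRCm38). Col4a4, which encodes the alpha-4 chain of the same network, lies beside it on the other strand, from 82448423 to 82586849. Both genes carried the same deposited count in every library, so their reads could not be told apart. The joint Col4a3/Col4a4 locus stood at 870, 1053 and 1271 CPM in the HET PBS libraries, at 743, 607, 953 and 997 CPM in the KO PBS libraries and at 515, 569, 809 and 665 CPM in the KO antimiR-21 libraries. Its log2 difference was -0.37 (SE 0.202, edgeR adjusted p = 0.77) between KO PBS and HET PBS, -0.37 (SE 0.188, adjusted p = 0.677) between KO antimiR-21 and KO PBS and -0.74 (SE 0.202, adjusted p = 0.44) between KO antimiR-21 and HET PBS. This locus therefore does not check the genotype labels, since reads of Col4a4 and of any transcript left from the targeted allele count in it. Col4a5 on chromosome X, which encodes the alpha-5 chain, stood at 196 ± 6.99 CPM in HET PBS (n = 3), 198 ± 23.6 in KO PBS (n = 4) and 185 ± 21.9 in KO antimiR-21 (n = 4). None of its differences passed the edgeR test.

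Ddx3y, an RNA helicase gene of the Y chromosome, separated the libraries within every group. It stood between 89.7 and 109.5 CPM in 2 of 3 HET PBS, 2 of 4 KO PBS and 1 of 4 KO antimiR-21 libraries, and at 0.172 CPM or less in the others. The first principal component of log2 CPM held 47% of the variance and followed this status, and the second held 13.1%. With Y-linked status as a term beside the groups, 1591 loci were higher and 985 lower in the 5 libraries with Y-linked reads than in the 6 without at an adjusted p under 0.05. The groups differ in the share of such libraries, which bears on every comparison.

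**Figure D1:**
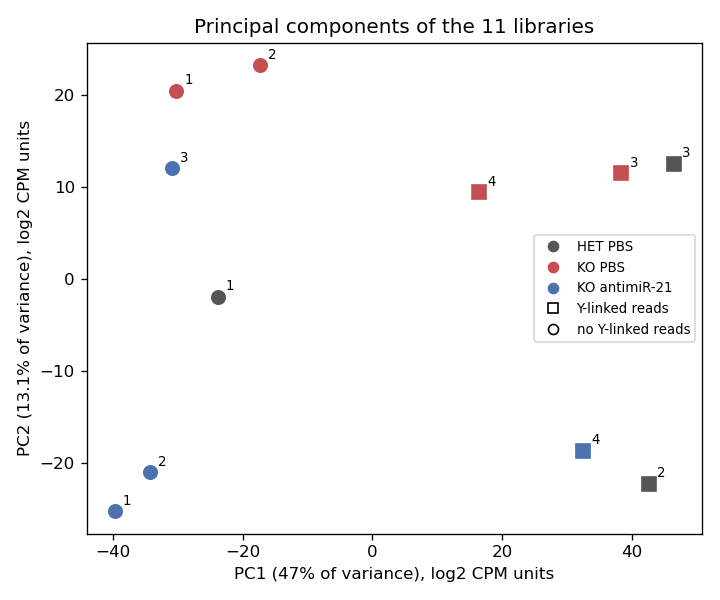
Principal components 1 (47% of the variance) and 2 (13.1%) of log2 CPM, in log2 CPM units, for the 11 libraries, colored by group and numbered by replicate. Squares are libraries with Y-linked reads, all at positive values of component 1, and circles are libraries without them, all at negative values.

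KO PBS was compared with HET PBS to ask how loss of Col4a3 changes the kidney at this age. Lcn2, the tubular injury marker lipocalin-2, stood at 64.2 ± 40.5 CPM in KO PBS (n = 4) and 3.82 ± 1.49 in HET PBS (n = 3). That is a log2 difference of 4.07 (SE 0.628), which did not pass the gene test (edgeR adjusted p = 0.247). The lowest adjusted p was 0.076, for Npy6r, a neuropeptide Y receptor gene on chromosome 18 from 44270127 to 44277700, at 4.70 ± 1.13 against 1.22 ± 0.181 CPM (log2 difference 1.94, SE 0.246). Fcrls, an Fc receptor-like gene expressed in microglia and related macrophages, stood at 2.04 ± 0.956 against 0.331 ± 0.0597 CPM. Rgs16, a regulator of G protein signalling, stood at 1.41 ± 0.687 against 0.286 ± 0.0343 CPM, and Adamts4, a protease that cleaves proteoglycans, at 5.03 ± 1.18 against 1.24 ± 0.125 CPM. These are the 5 genes with the smallest p, none past the adjusted threshold, and in each of them the KO PBS and HET PBS ranges did not overlap. With Y-linked status as a covariate edgeR called 3 loci higher in KO PBS, among them Npy6r (adjusted p = 0.0216) and Fcrls (0.0432), while Lcn2 (0.174), Rgs16 (0.0749) and Adamts4 (0.124) did not pass.

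Taken as lists, genes of injury and of the interstitium were higher in KO PBS. Of 34 tubular injury genes, 33 had positive differences (median log2 0.74) and 19 passed when adjusted over the list alone, against 0 when adjusted over all genes tested. They include Lcn2 and Dcdc2a, a doublecortin family gene (56.1 ± 12.3 against 23.2 ± 5.78 CPM). The list passed at an adjusted p of 5.46e-22 (camera, limma), with adjusted p = 0.205 with an estimated correlation. All 35 interstitial collagen and fibrosis genes had positive differences (median 0.75), and 18 passed adjusted over the list alone. Examples are Timp1, an inhibitor of matrix metalloproteases (6.58 ± 5.84 against 0.614 ± 0.317 CPM, with 15.3 in KO PBS replicate 1 and 3.26 to 4.04 in the others), and Lum, which encodes the collagen-binding proteoglycan lumican (6.15 ± 1.92 against 2.35 ± 0.483 CPM). The fibrosis list passed at 1.57e-21 and had adjusted p = 0.262 with an estimated correlation. The myofibroblast and pericyte list passed with a median of 0.29 (adjusted p = 0.372 with an estimated correlation). In it 5 of 17 genes passed adjusted over the list alone, among them Vim, the intermediate filament gene of mesenchymal cells (87.7 ± 27.7 against 50.7 ± 11.8 CPM), and Thy1, a surface marker of fibroblasts and T cells.

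Inflammatory lists were also higher in KO PBS. Of 22 cytokine and NF-kB responsive genes, 21 had positive differences (median log2 0.68) and 14 passed adjusted over the list alone. Among these are Cxcl1, a neutrophil chemoattractant (4.65 ± 2.99 against 1.23 ± 0.359 CPM), and Birc3, an NF-kB induced inhibitor of apoptosis (24.0 ± 5.45 against 15.1 ± 2.41 CPM). This list passed at 1.13e-15 (adjusted p = 0.205 with an estimated correlation). All 26 macrophage and monocyte genes had positive differences (median 0.68), with 2 past the threshold adjusted over the list alone. Its 2 members with the smallest p were Cd14, the lipopolysaccharide co-receptor (15.3 ± 8.31 against 6.45 ± 1.47 CPM), and Lyz2, the lysozyme of myeloid cells (45.9 ± 20.4 against 18.1 ± 8.73 CPM). The list passed at 1.01e-14 (adjusted p = 0.262 with an estimated correlation). The immediate early list (median 0.47) had 5 of 19 genes past the threshold adjusted over the list alone, among them the transcription factor genes Egr1 (13.5 ± 3.38 against 5.67 ± 1.39 CPM) and Egr2. It passed at 2.02e-10 (adjusted p = 0.205 with an estimated correlation). With Y-linked status as a covariate 12 macrophage, 16 cytokine and 6 immediate early genes passed adjusted over the list alone. Of tubular injury genes 16 did, against 19 without the covariate.

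Complement genes had a median log2 difference of 0.61 (adjusted p = 0.269 with an estimated correlation), with C3, the central complement component, at 186 ± 203 against 31.3 ± 18.2 CPM and C1qb at 20.7 ± 7 against 12.4 ± 3.75 CPM. C3 stood at 486, 132, 49.5 and 77.3 CPM in the KO PBS libraries, so its mean rests largely on replicate 1. By edgeR 0 of the 15 complement genes passed adjusted over the list alone, with 6 higher at an unadjusted p under 0.05. The lymphocyte list had a median of 0.47 (adjusted p = 0.372 with an estimated correlation), and Nkg7 of cytotoxic cells and Cd52, a leukocyte surface antigen, passed adjusted over the list alone. Of the neutrophil list 5 genes were tested (median 0.31, adjusted p = 0.358 with an estimated correlation). Lcn2, which injured tubules also express, was the 1 of them past the threshold adjusted over the list alone, and Mmp9, a gelatinase, stood at 0.931 ± 0.608 against 0.549 ± 0.346 CPM. Both Mmp9 means rest largely on replicate 1, at 1.84 against 0.529 to 0.701 in the other KO PBS libraries and at 0.944 against 0.302 and 0.400 in HET PBS. The TGF-beta and EGFR list had a median of 0.09 (adjusted p = 0.269 with an estimated correlation). The 2 of its 25 genes past the threshold adjusted over the list alone were Egr1 and the joint D030025P21Rik/Ltbp2 locus, which includes a TGF-beta binding protein gene (6.29 ± 5.05 against 0.728 ± 0.252 CPM). That locus stood at 13.8, 2.86, 3.70 and 4.85 CPM in the KO PBS libraries, so its mean rests largely on replicate 1. Podocyte genes had a median of 0.19 (adjusted p = 0.372 with an estimated correlation). Cdkn1c, a cell cycle inhibitor of mature podocytes, stood at 53.9 ± 11 against 30.1 ± 6.96 CPM, and Nes, which encodes the filament protein nestin, at 58.4 ± 11.3 against 38.1 ± 4.85 CPM. Both passed adjusted over the list alone. Smaller list differences that passed with a preset correlation were those of interferon response (median 0.26, adjusted p = 0.652 with an estimated correlation), antigen presentation (0.16, adjusted p = 0.638 with an estimated correlation) and cell cycle (0.28, adjusted p = 0.602 with an estimated correlation). Each had 0 genes past the threshold adjusted over the list alone by edgeR and 0, 0 and 1 higher genes at an unadjusted p under 0.05. Gbp2 and Ifi27l2a, both induced by interferon, the class II gene H2-Aa and the joint locus of Ciita, the class II transactivator, and the cell cycle genes Cenpa and Foxm1/Rhno1 were their members with the smallest p.

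Of the 4 tubule segment lists, proximal tubule and distal convoluted tubule were lower in KO PBS, and so were lists of mitochondrial and peroxisomal metabolism. Thick ascending limb (median log2 -0.02, though camera gives the direction as higher, adjusted p = 0.67) and collecting duct (-0.10, 0.131) did not pass. With Y-linked status as a covariate collecting duct passed as lower (camera adjusted p = 0.0184, and adjusted p = 0.403 with an estimated correlation). Of 29 proximal tubule genes 27 had negative differences (median log2 -0.30, camera adjusted p = 1.62e-06, and adjusted p = 0.205 with an estimated correlation). The joint locus of Slc34a1, the sodium phosphate cotransporter of the proximal tubule, stood at 5415 ± 394 CPM against 7203 ± 845 and that of Slc5a12, a lactate transporter, at 920 ± 74.8 against 1180 ± 98.0 CPM. All 20 tricarboxylic acid cycle genes had negative differences (median -0.16, adjusted p = 0.446 with an estimated correlation), with Ogdh, a subunit of oxoglutarate dehydrogenase, at 764 ± 73.1 against 940 ± 126 CPM. Peroxisome genes had a median of -0.16 (adjusted p = 0.372 with an estimated correlation), with Cat, which encodes catalase, at 989 ± 117 against 1216 ± 134 CPM and Ddo, D-aspartate oxidase, at 51.8 ± 4.08 against 64.0 ± 5.29 CPM. The fatty acid oxidation and PPAR-alpha list had a median of -0.16 (adjusted p = 0.372 with an estimated correlation). In it Cpt1a, the enzyme that commits fatty acids to mitochondrial oxidation, stood at 520 ± 27.0 against 666 ± 46.6 CPM. The joint Cdpf1/Ppara locus stood at 166 ± 19.4 against 235 ± 48.7 CPM, with 263, 263 and 179 CPM in the HET PBS libraries. An index of clock genes, described below, was 3.71, 4.1 and 1.87 in these and 1.76 to 2.07 in KO PBS. For this locus clock phase and genotype were therefore not told apart. The list score did not run this way in HET PBS (0.0024, -0.0663 and 0.0639). Gluconeogenesis and amino acid genes had a median of -0.17 (adjusted p = 0.372 with an estimated correlation), with a log2 difference of -0.27 for Aldh4a1, an enzyme of proline breakdown. Nuclear-encoded oxidative phosphorylation genes had a median of -0.09 (adjusted p = 0.692 with an estimated correlation). The distal convoluted tubule list, which did not pass with joint loci left out (camera adjusted p = 0.138), had one of -0.10 (adjusted p = 0.567 with an estimated correlation), with Slc8a1, a sodium calcium exchanger, at 123 ± 19.4 against 166 ± 62.1 CPM. Of 7 erythrocyte loci 4 were lower adjusted over the list alone (median -0.53, adjusted p = 0.205 with an estimated correlation), among them Hba-a1, alpha globin, at 0.430 ± 0.208 against 1.61 ± 0.325 CPM. In the other called lists of lower genes 0 passed adjusted over the list alone by edgeR, with 9 proximal tubule genes and 0 to 3 genes of the rest lower at an unadjusted p under 0.05.

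By edgeR 0 loci were higher and 0 lower in KO PBS at an adjusted p under 0.05. At an unadjusted p under 0.05, 606 were higher and 392 lower. Independent loci would give 719 by chance in both directions together, but loci share differences here. In 8 of 35 splits of these 7 libraries, the real one among them, at least as many loci had such a p, and the highest other split had 3398. DESeq2 called 72 higher and 12 lower, and limma-voom called 0 and 0. Of the 37 lists tested 22 passed with the preset correlation (14 higher, 8 lower), 0 with an estimated correlation and 0 with the directional test of fry (lowest adjusted p 0.0771). The mixed test of fry, which takes changes in either direction, passed for 4 of them: tubular injury (0.0242), immediate early (0.0242), erythrocyte (0.0269) and cytokines (0.0339). Among the 35 ways to split these 7 libraries into groups of the same sizes, 7 called at least as many. As list scores, tubular injury was 0.849 higher in KO PBS, neutrophil 0.983, TGF-beta and EGFR 0.284 and immediate early 0.588. Each had an exact p of 0.0286, the smallest that the 35 arrangements allow, and an adjusted p over 37 lists of 0.264 by exact test. The neutrophil score holds 5 genes with a median of 0.31, beside 4.07 for Lcn2, and the TGF-beta and EGFR median was 0.09, beside 3.13 for the Ltbp2 locus. These scores therefore rest on few genes. The scores of KO PBS replicate 1 were the highest of its group for tubular injury (1.499 against 0.518 to 0.774 in the others) and for macrophages (1.29 against 0.284 to 0.550).

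**Figure D2:**
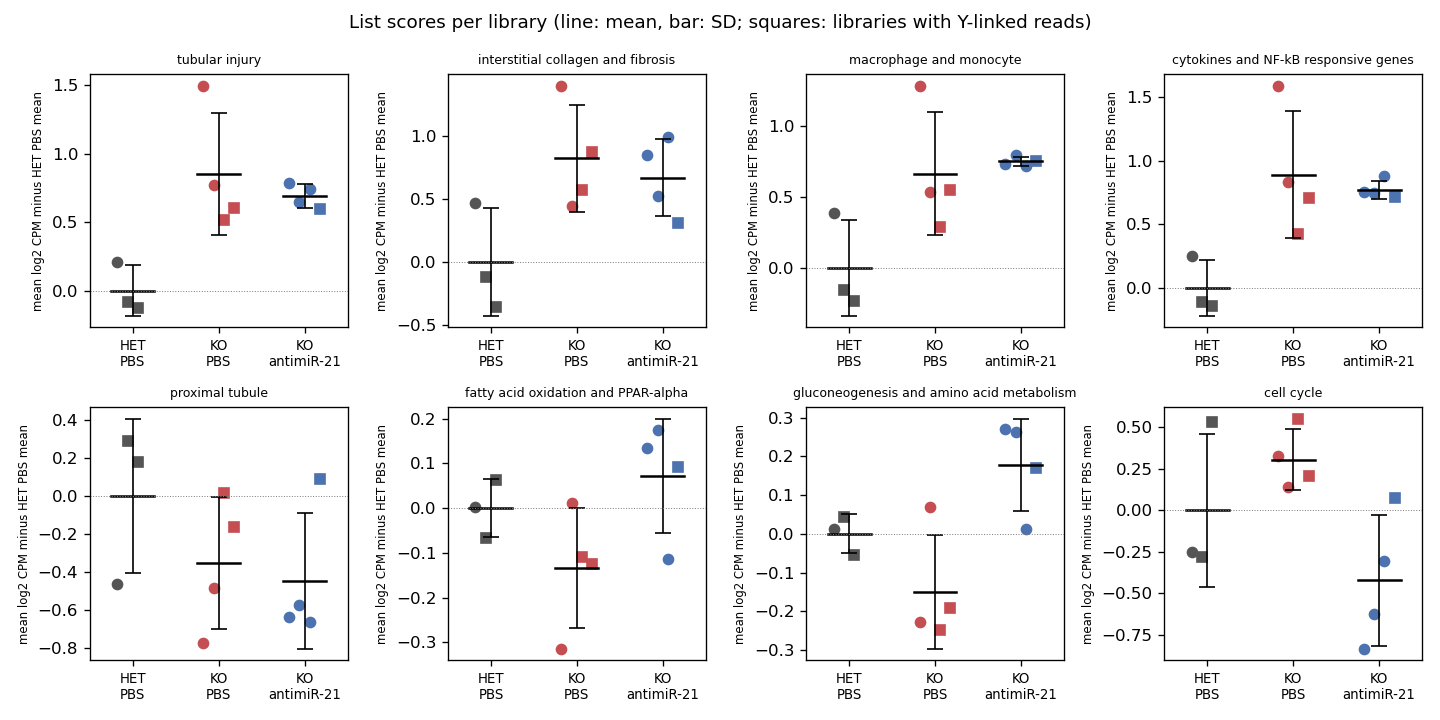
Score of 8 gene lists per library, as the mean log2 CPM of the list's genes minus the HET PBS mean, for HET PBS (n = 3), KO PBS (n = 4) and KO antimiR-21 (n = 4), with black lines at group means and bars of SD. Squares are libraries with Y-linked reads. Tubular injury scores are 0.849 higher in KO PBS than in HET PBS, and cell cycle scores 0.421 below the HET PBS mean in KO antimiR-21 and 0.305 above it in KO PBS.

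KO antimiR-21 was compared with KO PBS to ask what inhibition of miR-21 changes in the knockout kidney. The cell cycle list was lower in KO antimiR-21. Of 33 genes 30 had negative differences (median log2 -0.78), and 20 passed adjusted over the list alone against 0 adjusted over all genes tested. Examples are Ccnb2, the mitotic cyclin B2 (7.74 ± 2.87 against 17.1 ± 3.89 CPM, log2 difference -1.14, SE 0.292), and the joint locus of Foxm1, a transcription factor of mitotic genes (27.8 ± 2.29 against 37.0 ± 2.66 CPM, log2 difference -0.41, SE 0.103). The list passed at an adjusted p of 4.17e-17 (camera, limma) and had adjusted p = 0.984 with an estimated correlation. Its score was -0.421 ± 0.395 in KO antimiR-21 (n = 4) and 0.305 ± 0.182 in KO PBS (n = 4), without overlap, with an exact permutation p of 0.0286, the smallest that this design allows, and 0.933 adjusted over the 37 lists. It differed by -0.817 among the libraries without Y-linked reads (3 KO antimiR-21, 2 KO PBS) and by -0.305 among those with them (1 and 2). The scores were -0.832, -0.623, -0.303 and 0.0734 in KO antimiR-21, 0.326, 0.137, 0.552 and 0.204 in KO PBS and -0.252, -0.281 and 0.533 in HET PBS.

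Of the metabolic lists 3 were higher in KO antimiR-21 with the preset correlation, each with adjusted p = 0.984 with an estimated correlation. Oxidative phosphorylation (median -0.05, 42 of 54 genes negative, camera adjusted p = 0.093) and the tricarboxylic acid cycle (median 0.02, 0.552) did not pass. As list scores the 3 differed with an exact p of 0.0571 (gluconeogenesis and amino acids), 0.0857 (fatty acid oxidation) and 0.314 (peroxisome). KO antimiR-21 replicate 3, the library of its group with the lowest clock index (2.49), had its lowest score in each, at 0.0136, -0.114 and -0.264. The others were at 0.17 to 0.269, 0.0926 to 0.175 and -0.0663 to 0.107. The gluconeogenesis and amino acid list had a median log2 difference of 0.17, with 3 of 25 genes past the threshold adjusted over the list alone. With Y-linked status as a covariate 10 of its genes passed as higher and 1 as lower. Prodh2, hydroxyproline dehydrogenase, stood at 318 ± 81.6 against 205 ± 24.8 CPM. The list passed at 6.40e-05 (adjusted p = 0.984 with an estimated correlation). The fatty acid oxidation and PPAR-alpha list (median 0.16, 2 of 32 genes adjusted over the list alone, and 7 with that covariate) passed at 0.00281 (adjusted p = 0.984 with an estimated correlation). Its joint Cdpf1/Ppara locus, which includes the gene of the lipid-sensing receptor PPAR-alpha, stood at 277 ± 48.3 against 166 ± 19.4 CPM (log2 difference 0.74, SE 0.156, edgeR adjusted p = 0.312). In the HET PBS libraries it stood at 263, 263 and 179 CPM. The Acaa1b/Dlec1 locus, which includes a peroxisomal thiolase gene, stood at 991 ± 245 against 568 ± 106 CPM. The peroxisome list (median 0.08, adjusted p = 0.984 with an estimated correlation) had 1 of 29 genes past the threshold adjusted over the list alone, Pxmp2, a peroxisomal membrane channel (89.1 ± 16.4 against 57.5 ± 8.39 CPM). The interferon response list had a median of 0.22 (adjusted p = 0.984 with an estimated correlation), with Ifi44 at 29.4 ± 6.07 against 21.6 ± 3.46 CPM. This list did not pass with Y-linked status as a covariate. The basement membrane list was lower (median -0.12, adjusted p = 0.984 with an estimated correlation), with the joint Col4a1/Col4a2 locus at 1146 ± 222 against 1506 ± 208 CPM and the joint locus of Nid2, a nidogen, at 137 ± 5.58 against 155 ± 2.42 CPM. Its call depends on joint loci, since without them the list did not pass (camera adjusted p = 0.224), and it was lost in 4 of 22 settings, beside the estimated correlation and fry. In these last lists 0 genes passed adjusted over the list alone by edgeR, with 1 interferon gene higher and 3 basement membrane loci lower at an unadjusted p under 0.05.

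The injury and fibrosis lists did not pass between the treatments. Tubular injury had a median log2 difference of -0.22 (camera adjusted p = 0.0715), interstitial collagen and fibrosis -0.14 (0.0711) and macrophage and monocyte -0.02 (0.528). With Y-linked status as a covariate the first 2 passed as lower in KO antimiR-21, at adjusted p of 0.000761 for tubular injury and 0.000153 for fibrosis (camera), with adjusted p = 0.98 with an estimated correlation for both. Cytokine and NF-kB genes also passed then as lower (0.0295) and proximal tubule genes as higher (0.0412), each with adjusted p = 0.98 with an estimated correlation. Among libraries without Y-linked reads (3 KO antimiR-21, 2 KO PBS) the scores differed by -0.41 for tubular injury, -0.132 for fibrosis and -0.42 for cytokines. Among those with them (1 and 2) they differed by 0.0339, -0.41 and 0.148, so tubular injury and cytokines went opposite ways. For proximal tubule the differences were 0.00414 and 0.162. With joint loci left out tubular injury passed without the covariate (0.0296). Of the miR-21 targets reported before, 19 were tested, with a median of 0.02 (camera adjusted p = 0.528). The 1 of them past the threshold adjusted over the list alone was the Cdpf1/Ppara locus (log2 difference 0.74, edgeR adjusted p = 0.312 over all genes). Spry1, an inhibitor of receptor tyrosine kinase signalling, stood at 24.1 ± 6.95 against 24.7 ± 3.53 CPM (edgeR adjusted p = 0.982), and Reck, an inhibitor of matrix metalloproteases, at 21.9 ± 3.63 against 21.3 ± 2.32 CPM (0.965). Vmp1 on chromosome 11 (86583865 to 86683836), a gene of autophagy whose annotated span holds Mir21a, stood at 167 ± 20.1 against 205 ± 9.91 CPM (log2 difference -0.29, SE 0.100, adjusted p = 0.458). None of the 5 genes with the smallest p passed. They are Rnf167, a ubiquitin ligase (158 ± 14.7 against 109 ± 7.75 CPM), and Nr1d2, a nuclear receptor of the circadian clock (189 ± 24.5 against 120 ± 2.76 CPM). The others are Insig1, a regulator of sterol synthesis (58.8 ± 3.29 against 37.8 ± 6 CPM), Fpr2, a formyl peptide receptor (1.60 ± 0.179 against 0.316 ± 0.140 CPM) and an unnamed locus. An index of 6 clock output genes minus 5 genes of the opposite phase was chosen after Nr1d2 was seen and leaves it out. Its output genes include the joint Nr1d1/Thra locus, whose reads cannot be assigned to Nr1d1. This index was 3.76 ± 0.87 in KO antimiR-21 (n = 4) and 1.90 ± 0.137 in KO PBS (n = 4), with an exact permutation p of 0.0286. The index was 3.71, 4.1 and 1.87 in HET PBS. Replicate 3 there, the library with the lowest index, had the highest cell cycle score and the lowest Cdpf1/Ppara value of its group. In KO antimiR-21 replicate 3 had the lowest index (2.49) and the lowest Cdpf1/Ppara value (311, 324, 224 and 248 CPM in replicates 1 to 4), while replicate 4 (index 3.87) had the highest cell cycle score.

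By edgeR 0 loci were higher and 0 lower in KO antimiR-21 than in KO PBS (684 higher and 497 lower at an unadjusted p under 0.05, lowest adjusted p 0.268), where DESeq2 called 84 and 54 and limma-voom 0 and 0. Without KO antimiR-21 replicate 3 edgeR called 16 higher. Of 37 lists 6 passed (4 higher, 2 lower), with 0 by an estimated correlation and 0 by fry (lowest adjusted p 0.623), and 34 of the 35 splits of these 8 libraries called at least as many.

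Genes with a site for miR-21 in their 3 prime UTR are candidates for direct targets released by an inhibitor. A sequence match alone does not make a gene a target, and how small a release could be detected was not tested. The 854 tested genes with a match to the 7-base miR-21 seed site ATAAGCT had a median log2 difference of -0.01 between KO antimiR-21 and KO PBS, and the 8930 genes without one 0.00 (-0.0019). Matched on UTR length and expression, site genes were shifted by -0.00596 on the log2 scale, with an exact two-sided permutation p of 0.6 over 70 assignments of the 8 KO libraries (SD over assignments 0.0111). Among 420 words of the same base composition this shift lay at percentile 63.8, and the words ranged from -0.0344 to 0.0246.

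KO antimiR-21 was compared with HET PBS to ask which differences from the heterozygous kidney were present under treatment. Fcrls was the 1 locus past the threshold, at 4.89 ± 1.32 CPM in KO antimiR-21 (n = 4) against 0.331 ± 0.0597 in HET PBS (n = 3), a log2 difference of 3.84 (SE 0.428, edgeR adjusted p = 0.0201). It falls just outside the rule for named genes, because its mean was below 5 CPM, and is named because it was the only call. The call was lost when any library of this comparison except KO antimiR-21 replicate 4 was left out. By edgeR 0 loci were lower, with 725 higher and 433 lower at an unadjusted p under 0.05. DESeq2 called 65 higher and 9 lower, and limma-voom 0 and 0.

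Injury and immune lists were higher in KO antimiR-21 than in HET PBS as well. Tubular injury genes had a median log2 difference of 0.54 and 13 of 34 passed adjusted over the list alone. Lcn2 stood at 46.6 ± 15.0 against 3.82 ± 1.49 CPM and Cd44, a hyaluronan receptor of injured tubules and leukocytes, at 7.33 ± 0.800 against 2.89 ± 0.402 CPM (list adjusted p = 1.32e-12, and adjusted p = 0.382 with an estimated correlation). Macrophage and monocyte genes had a median of 0.73 and 11 of 26 passed adjusted over the list alone. Ms4a7 stood at 3.85 ± 0.571 against 1.10 ± 0.581 CPM and Itgam, an integrin of myeloid cells, at 8.53 ± 0.247 against 3.29 ± 0.618 CPM (2.77e-13, and adjusted p = 0.382 with an estimated correlation). Interstitial collagen and fibrosis genes had a median of 0.52, with 7 of 35 past the threshold adjusted over the list alone, among them Ctgf, a matrix-associated growth factor (154 ± 33.7 against 61.6 ± 28.6 CPM), and Dcn, which encodes decorin (101 ± 24.0 against 42.3 ± 14.1 CPM). This list passed at 4.12e-12 (adjusted p = 0.417 with an estimated correlation). Complement genes had a median of 0.72, with 7 of 15 past the threshold adjusted over the list alone, among them C3ar1, the receptor of C3a (6.45 ± 0.812 against 2.35 ± 1.15 CPM; adjusted p = 0.382 with an estimated correlation). Cytokine and NF-kB genes had a median of 0.64 and 6 of 22 passed adjusted over the list alone, with Ccl7, a monocyte chemoattractant, at 0.911 ± 0.858 against 0.0760 ± 0.0460 CPM (2.19 in KO antimiR-21 replicate 1 and 0.332 to 0.589 in the others; adjusted p = 0.382 with an estimated correlation). With Y-linked status as a covariate fewer genes passed adjusted over the list alone by edgeR. They were 2 of tubular injury (median 0.41), 10 of macrophages (0.60), 5 of fibrosis (0.39), 1 of complement (0.58) and 0 of cytokines (0.42), where 11 cytokine genes were higher at an unadjusted p under 0.05 without the covariate.

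The immediate early list had a median of 0.46 (adjusted p = 0.382 with an estimated correlation), with Egr1 at 12.7 ± 5.29 against 5.67 ± 1.39 CPM. The myofibroblast and pericyte list had one of 0.35 (adjusted p = 0.417 with an estimated correlation), with Meg3, a noncoding RNA of mesenchymal cells, at 2.12 ± 0.252 against 0.985 ± 0.197 CPM. Podocyte genes had a median of 0.30 (adjusted p = 0.439 with an estimated correlation), with Cdkn1c at 60.2 ± 8.92 against 30.1 ± 6.96 CPM. The interferon response list had a median of 0.46 (adjusted p = 0.417 with an estimated correlation), with Isg15, a ubiquitin-like protein gene, at 4.03 ± 0.752 against 2.36 ± 0.766 CPM. Antigen presentation had one of 0.37 (adjusted p = 0.538 with an estimated correlation), lymphocytes 0.45 (adjusted p = 0.538 with an estimated correlation) and neutrophils 0.21 (adjusted p = 0.417 with an estimated correlation). The miR-21 targets reported before had a median of 0.12 (camera adjusted p = 0.0452, and adjusted p = 0.417 with an estimated correlation). Its members with the smallest p were Btg2, an antiproliferative gene (32.9 ± 5.78 against 23.7 ± 3.39 CPM), and Reck (21.9 ± 3.63 against 17.6 ± 2.47 CPM). This list and the neutrophil list did not pass with Y-linked status as a covariate. With the covariate the medians were 0.335 (immediate early), 0.213 (myofibroblast and pericyte), 0.0828 (podocyte), 0.258 (interferon response) and 0.198 (antigen presentation). They were 0.245 for lymphocytes, -0.0812 for neutrophils and 0.0762 for miR-21 targets.

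Lower in KO antimiR-21 than in HET PBS were the lists of oxidative phosphorylation (median -0.12, with 53 of 54 genes negative and adjusted p = 0.594 with an estimated correlation) and of the tricarboxylic acid cycle (-0.14, adjusted p = 0.544 with an estimated correlation). So were those of proximal tubule (-0.18, adjusted p = 0.417 with an estimated correlation) and cell cycle (-0.44, adjusted p = 0.47 with an estimated correlation). Their members include Cox5a, a subunit of cytochrome oxidase, at 266 ± 28.3 against 318 ± 34.3 CPM, Keg1 of the proximal tubule at 1291 ± 317 against 2102 ± 675 CPM and Ccnb1, cyclin B1, at 2.83 ± 1.497 against 6.33 ± 4.63 CPM (11.6 in HET PBS replicate 3, 4.21 and 3.16 in the others). The sterol list was lower as well (-0.14, adjusted p = 0.439 with an estimated correlation), with a log2 difference of -0.52 for Nsdhl, an enzyme of cholesterol synthesis. The erythrocyte list was also lower (-0.44, adjusted p = 0.382 with an estimated correlation). The male kidney list had a median of -1.06 (adjusted p = 0.544 with an estimated correlation), with Cyp7b1, an oxysterol hydroxylase, at 3.03 ± 2.85 against 11.2 ± 15.6 CPM. The direction of Cyp7b1 rests on HET PBS replicate 2 (29.2 CPM, and 1.97 and 2.31 in the others), and without it the log2 difference was 0.501. In these groups 1 of 4 KO antimiR-21 and 2 of 3 HET PBS libraries had Y-linked reads. With this status as a covariate the medians were -0.287 for male kidney, -0.107 for proximal tubule and -0.287 for cell cycle. They were -0.0823 for oxidative phosphorylation, -0.0821 for the tricarboxylic acid cycle, -0.153 for sterol and -0.311 for erythrocyte. Of 37 lists 20 passed (13 higher, 7 lower), with 0 by an estimated correlation and 0 by fry (lowest adjusted p 0.143), and 6 of the 35 splits of these 7 libraries called at least as many.

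The disease score asks whether treated knockout kidneys lay closer to the heterozygous ones. As designed it rests on a single gene, Npy6r, the only one to differ between HET PBS and the 8 KO libraries at an adjusted p under 0.05. Its score was 1.75 ± 0.246 in KO antimiR-21 (n = 4) and 1.85 ± 0.344 in KO PBS (n = 4), a difference of -0.102 (exact permutation p = 0.714). With 262 genes at an unadjusted p under 0.01 (228 higher and 34 lower in KO), a threshold chosen after the data were seen, the score was 0.981 ± 0.111 in KO antimiR-21 and 0.982 ± 0.329 in KO PBS. That is a difference of -0.000583 (exact permutation p = 1). HET PBS libraries scored 0 ± 0.205 by construction of the mean. Choosing genes by HET PBS against all 8 KO libraries favors genes altered in both KO groups. A gene that treatment brought back to the HET PBS level was less likely to be chosen. A difference near 0 in either score therefore cannot show that treatment brought no genes back.

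The reversal asks how many genes of KO PBS against HET PBS moved the other way in KO antimiR-21 against KO PBS. By edgeR 0 genes passed the adjusted threshold in the former, so it was taken over its genes at an unadjusted p under 0.01, 262 as well but another set than that of the score, a choice made after the data were seen. Of these 219 (83.6%) moved the opposite way. Simulated unchanged groups that share the KO PBS libraries gave 89.1% on average over 50 sets. Each locus in these sets was drawn independently, without the differences by Y-linked status that loci share in these data. The simulated values here and below therefore need not hold for the real libraries. With the KO PBS libraries divided between the comparisons the share was 60.8% on average and ranged from 31.8% to 83.9% over 6 divisions. Over all genes, which are not independent replicates, the fold changes of both comparisons had a correlation of -0.28 (simulated -0.456) and a covariance of -0.0336 (simulated -0.0349, a difference of 0.00136).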

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

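Among the tests in this part, those within Y-linked status and that of proximal tubule share were chosen only after the result was seen. The clock test was set before its own result, but after Nr1d2 and Per3 had been seen.

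In groups of 4, a library was singled out when it stood apart from the other 3, measured as its gap to the nearest of them over the whole range of the group. Of 238 groups examined 25 were singled out. Independent values would give about 1 in 20 by chance (11.9). List scores and genes share members and libraries here, so the count of 25 does not show an excess over chance. KO antimiR-21 replicate 4, the only library of its group with Y-linked reads, stood apart for Ddx3y (1), the male kidney score (0.897), the proximal tubule score (0.882), the podocyte score (0.943), Coq10a/Cs (0.928), Birc3 (0.894), Cycs (0.842), Nes (0.84) and C1s (0.833). Its male kidney score was 0.947 against -2.64 to -2.27 in the others, its proximal tubule score 0.087 against -0.661 to -0.573 and its podocyte score -0.0472 against 0.324 to 0.346.

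KO PBS replicate 1 stood apart for the injury and leukocyte genes Timp1 (0.863), Cd44 (0.935), Cd14 (0.853) and Itgam (0.882), for the neutrophil score (0.833), for Coq10a/Cs (0.948) and for the peroxisome (0.864) and sterol (0.894) scores. Timp1 was at 3.95 log2 CPM in it against 1.74 to 2.04 in the others, and its neutrophil score was 1.54 against 0.719 to 0.856. KO PBS replicate 2 stood apart for BC017158/Slc5a2 (0.834), Col4a5 (0.854) and Pex6 (0.844), and KO PBS replicate 3 for Ccnb1 (0.888). In KO antimiR-21, replicate 3 stood apart for Cpt1a (0.891) and Npy6r (0.935), replicate 2 for Lcn2 (0.915) and replicate 1 for Cxcl1 (0.852).

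The higher injury, fibrosis and macrophage scores of KO PBS averaged 0.778 ± 0.421 (n = 4) against 0 ± 0.314 in HET PBS (n = 3). A smaller share of proximal tubule RNA could raise every other cell type alike. The 3 scores exceeded those of endothelium, thick ascending limb and collecting duct by 0.801 more in KO PBS than in HET PBS (exact p = 0.0286). The lists on both sides were chosen after their differences were seen, so this p cannot test that cause. The endothelium, thick ascending limb and collecting duct scores themselves differed by 0.00735, 0.0161 and -0.0916, where that cause would raise them. Unequal numbers of libraries with Y-linked reads could also matter, and the difference was 0.633 without such reads, where HET PBS has 1 library and nothing is settled, and 0.745 with them (2 against 2). With this status as a covariate the median log2 differences of the 3 lists were 0.64, 0.69 and 0.61, against 0.74, 0.75 and 0.68 without it, which argues against it as the whole cause but leaves part of it open. For the lists in this comparison chance cannot be excluded, since 7 of 35 splits called as many as the real 22 and the highest other split called 25.

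The lower cell cycle list in KO antimiR-21 than in KO PBS could come from unequal numbers of libraries with Y-linked reads. Among arrangements that keep Y-linked status the exact p was 0.0333, but the stratum with such reads holds 1 KO antimiR-21 library, so this p rests in part on it. With the status as a covariate the list median was -0.73 against -0.78 without, which argues against it as the whole cause. A single library could also carry the result, but the difference nearest 0 with any library left out was -0.589, against -0.726 with all 8. The index of clock genes also parted the groups, at 1.76 to 2.07 in KO PBS and 2.49 to 4.35 in KO antimiR-21. Clock phase and treatment were therefore not told apart for this list. In HET PBS the library with the lowest index (1.87) had the highest score (0.533). In KO antimiR-21 the highest score (0.0734) was that of replicate 4, with an index of 3.87. For the lists in this comparison chance cannot be excluded, since 34 of 35 splits called as many as the real 6 and the highest other called 26.

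Nr1d2 and Per3 were higher in KO antimiR-21 than in KO PBS, without passing the gene test. Kidneys collected at different times of day could give this, and then other clock genes should move too. The index of 6 output minus 5 opposite-phase genes, without these 2, differed by 1.86 (exact p = 0.0286), and the opposite-phase genes alone by -1.06 (SE 0.265), in line with a difference in clock phase. The labels give no collection times, and an effect of the treatment on the clock would give the same values, so these data do not separate the causes.

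Splits of the same libraries into other groups of the same sizes were also compared on genes called. In KO PBS against HET PBS 35 of 35 splits called as many as the real 0, and the highest other called 407. In KO antimiR-21 against KO PBS 35 of 35 called as many as the real 0, and the highest other called 1. Any split meets a count of 0, so these 2 counts say nothing about chance. In KO antimiR-21 against HET PBS 2 of 35 called as many as the real 1, and the highest other called 3435. For its lists 6 of 35 called as many as the real 20, and the highest other called 26. Chance cannot be excluded for these 2 results of KO antimiR-21 against HET PBS. The splits with 407 and 3435 genes part the libraries exactly by Y-linked reads, which points to a structure of the samples other than the labelled groups.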

How the results depend on the processing

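List calls made with the preset correlation were mostly kept, but all of them were lost with an estimated correlation, by the directional test of fry and by exact permutation adjusted over the lists, and gene counts depended on the tool. Of the list calls tested one by one under alternatives, 954 kept their side of the threshold and 156 did not, and of the named genes reported here 2149 stayed the same, 102 passed where they had not, 7 no longer passed and 12 reversed. The effect of depth was not tested. The gene test recovered 60.3% of 2-fold changes simulated for KO PBS against HET PBS, with loci drawn independently. Added alternatives, which include DESeq2 with the Y-linked (sex) covariate, rows as deposited and the sex covariate for scores, were chosen after seeing the data. No value came from the disease score with genes of HET PBS against KO PBS alone, at an adjusted p under 0.01, or without HET PBS replicates 1, 2 or 3, KO PBS replicate 3 or KO antimiR-21 replicates 1, 3 or 4, nor from the reversal at the adjusted threshold, because 0 genes passed.

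The choice of tool moved gene counts most. DESeq2 called 72 higher and 12 lower in KO PBS against HET PBS, 84 and 54 in KO antimiR-21 against KO PBS and 65 and 9 in KO antimiR-21 against HET PBS, and 42 named genes against 1 by edgeR, counted here and below over all genes that the rule takes and Fcrls in KO antimiR-21 against HET PBS, which is outside the rule and is the 1. With the sex covariate DESeq2 called 129 and 47, 183 and 111, and 65 and 24, with 50 named genes. By edgeR with the sex covariate 3 loci were higher in KO PBS than in HET PBS and 2 in KO antimiR-21 than in HET PBS, with 3 named genes. On the deposited log2 matrix limma called 1 and 2 higher in these comparisons and 2 named genes, and limma-voom 0 with 0 named genes. For these the cause was not tested. By camera with an estimated correlation, by the directional test of fry and by exact permutation adjusted over the lists, 0, 0 and 0 lists passed in each comparison, against 22, 6 and 20. The list calls least stable were miR-21 targets in KO antimiR-21 against HET PBS (lost in 10 of 21 settings), neutrophils in the same comparison (7 of 21) and distal convoluted tubule in KO PBS against HET PBS (6 of 21). With joint loci left out, distal convoluted tubule in KO PBS against HET PBS (adjusted p = 0.138) and basement membrane in KO antimiR-21 against KO PBS (0.224) no longer passed. Tubular injury in the latter (0.0296) and miR-21 targets in the former (0.0437) then passed.

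With replicate number as a block, edgeR called 2 higher in KO PBS against HET PBS, 18 higher and 8 lower in KO antimiR-21 against KO PBS, and 3 higher and 1 lower in KO antimiR-21 against HET PBS, with 8 named genes, and the reversal was 72.1%. The correlation of deviations between libraries of the same number was 0.63, -0.44 and 0.39 for KO PBS and HET PBS. It was 0.36, 0.3, -0.21 and 0.29 for KO antimiR-21 and KO PBS, and 0.48, -0.3 and -0.09 for KO antimiR-21 and HET PBS. Each positive value came from libraries alike in Y-linked status and each negative one from libraries that differ in it. Over all libraries of different groups the median was 0.35 for those alike in this status and -0.34 for the rest. These values therefore cannot show a pairing or exclude one.

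With each library left out in turn, KO PBS against HET PBS gave 0 to 2 higher loci (2 without KO PBS replicate 2), 0 to 0 lower and 17 to 24 lists. KO antimiR-21 against KO PBS gave 0 to 16 higher (16 without KO antimiR-21 replicate 3), 0 to 0 lower and 6 to 8 lists. KO antimiR-21 against HET PBS gave 0 to 1 higher, 0 to 0 lower and 17 to 25 lists. For these ranges the cause was not tested.

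Differences near 0 changed sign, and the cause was not tested. The disease score of Npy6r ran from -0.255 to 0.0341 (without KO PBS replicate 4). The score of 262 genes ran from -0.0495 to 0.161, and was positive without KO PBS replicate 1 (0.161), HET PBS replicates 1 (0.0435) and 2 (0.0163) and KO antimiR-21 replicate 4 (0.0394), with a stricter filter (0.00332) and with the sex covariate (0.0262). The reversal ran from 64.8% (without KO PBS replicate 1) to 94.1% (without HET PBS replicate 3), was 69.1% without HET PBS replicate 1 and averaged 60.8% with KO PBS libraries split between the comparisons, which removes the shared libraries. The shift of seed site genes ran from -0.0169 to 0.000674 (without KO PBS replicate 3) and was 0.00123 with 8mer sites only.

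Some named genes changed sign, and the cause was not tested. Col4a5 in KO PBS against HET PBS ran from -0.0216 (without KO PBS replicate 4) to 0.119, with -0.00554, -0.00171 and -3.81e-05 without KO PBS replicate 3, HET PBS replicate 1 and KO PBS replicate 1. Ddx3y there ran from -1.13 to 0.0243 (without HET PBS replicate 3). In KO antimiR-21 against KO PBS, Spry1 ran from -0.244 to 0.0758 (without KO antimiR-21 replicate 4), with 0.0595 and 0.00851 without KO PBS replicate 4 and KO antimiR-21 replicate 1. Reck ran from -0.0516 (without KO antimiR-21 replicate 3) to 0.0966, with -0.0282 and -0.0029 without KO PBS replicate 2 and KO antimiR-21 replicate 1. Cyp7b1 in KO antimiR-21 against HET PBS ran from -2.8 to 0.501 (without HET PBS replicate 2).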

Other observations

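Y-linked status was the strongest difference between these kidneys, and the genes below were chosen after it was seen. In the 5 libraries with Y-linked reads, against the 6 without, Slco1a1, an organic anion transporter, was higher at 409 ± 203 against 0.425 ± 0.187 CPM (edgeR adjusted p = 2.51e-05). The cytochrome P450 gene Cyp2j13 was higher at 434 ± 143 against 1.91 ± 0.908 CPM (8.29e-07), and Slc22a30, of a family of organic anion transporters, at 429 ± 89.9 against 13.3 ± 5.61 CPM (5.18e-08). Lower were Cyp4a14, a fatty acid hydroxylase (137 ± 79.1 against 823 ± 249 CPM, 0.011), Slc7a12, an amino acid transporter (172 ± 102 against 555 ± 156 CPM, 0.0142), Hpd, an enzyme of tyrosine breakdown (96.3 ± 73.3 against 657 ± 440 CPM, 0.000373), and Gsta4, a glutathione transferase (29.8 ± 7.42 against 125 ± 27.3 CPM, 0.000233). The male kidney list was higher (median log2 2.62, 9 of 12 genes up and 1 down, camera adjusted p = 8.05e-10, and adjusted p = 0.069 with an estimated correlation). Its lower gene was Gsta4. The female kidney list, which holds Cyp4a14 and Slc7a12, did not pass (camera adjusted p = 0.258). Its median log2 was 0.41, with 5 of 12 genes up and 4 down in libraries with Y-linked reads.

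Other lists moved with Y-linked status beside the groups. Interferon response genes were lower in libraries with Y-linked reads (median log2 -0.55, 8 of 22 genes down, adjusted p = 0.491 with an estimated correlation). Podocyte genes were lower as well (median -0.30, 10 of 24 down, adjusted p = 0.217 with an estimated correlation), and so were interstitial collagen and fibrosis genes (median -0.42, 7 of 35 down, adjusted p = 0.491 with an estimated correlation). Tubular injury genes (median -0.34, 5 of 34 down) and macrophage genes (median -0.40, 3 of 26 down) were lower, each with adjusted p = 0.491 with an estimated correlation. Cell cycle genes were higher (median 0.45, 4 of 33 up, adjusted p = 0.491 with an estimated correlation). Proximal tubule genes were higher (median 0.14, 12 up and 3 down, adjusted p = 0.491 with an estimated correlation). Whether the differences between groups depend on Y-linked status cannot be settled here. HET PBS has 1 library without Y-linked reads and KO antimiR-21 has 1 with them.

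Clock genes differed between KO antimiR-21 and KO PBS in size but not past the gene test. Per3 stood at 112 CPM in KO antimiR-21, 37.5 in KO PBS and 95.7 in HET PBS (log2 difference between treatments 1.58, edgeR adjusted p = 0.327), Tef at 623, 320 and 546 CPM and Hlf at 177, 95 and 166 CPM, the last 2 being transcription factors of clock output. Arntl and Npas2, which drive the clock in the opposite phase, stood at 8.42, 25.7 and 11.6 CPM and at 5.35, 20.2 and 9.94 CPM. Cry1, listed with the opposite phase, had a difference the other way (0.49). The index stood at 2.07, 1.93, 1.76 and 1.82 in the KO PBS libraries, at 4.35, 4.32, 2.49 and 3.87 in KO antimiR-21 and at 3.71, 4.1 and 1.87 in HET PBS.

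On the second principal component the 6 libraries with an index of 2.49 or less stood at 9.42 to 23.21, and the other 5 at -25.24 to -1.92. This was seen after the index was made and was not tested.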
